A study of Homo sapiens with 4 samples.

How the data were processed

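The series measured gene expression by array in Huh7, an established human hepatocellular carcinoma cell line. Huh7 cells were separated by flow cytometry into cells that carry the surface protein CD133 (the product of PROM1) and cells that do not. Total RNA of each population was extracted with Trizol, amplified and labelled with biotin, per the labels' protocols. The deposited table holds 4 columns: each population appears once with MAS5 values and once with RMA values. These were taken as 1 array per population summarized by different algorithms, because the labels differ only in the algorithm and no label speaks of repeated sorts. MAS5 and RMA values were therefore never treated as replicates.

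The MAS5 columns hold signal intensity per probe set on a linear scale, per the labels and the deposited values. MAS5 and GCOS are named in the submitters' processing notes, without versions. The mean signal after trimming 2% from each end was 500.1 on both deposited arrays, so the authors' values carry a global scaling to a common target. The RMA columns hold log2 values, per the labels and the deposited range of 1.33 to 14.2. RMA combines background correction, quantile normalization and a fit over the probes of a set. The software behind the RMA values, its version, and which arrays were normalized together are not given in the sources used here. Quantile normalization gives both arrays nearly the same distribution of values, so a global shift between the populations could not be seen on either scale. Detection calls, scan dates and scanner files were not used here.

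The array has 54675 probe sets. The platform annotation paired 41097 of them with exactly 1 gene symbol, 1801 with several and listed none for 11777. Symbols were updated through the Entrez gene number to those of assembly GRCh38.p14, which matched 41043 probe sets. Probe sets with several symbols or none named no gene. No coordinates are given, since the files name no genome build. Each of the 19775 named genes was represented by its probe set of highest mean RMA value.

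From these values the difference CD133+ minus CD133- was computed per gene on the log2 scale. RMA was the main scale. A gene was called detected when the brighter of its RMA values lay above 4.86, the median of that quantity over all probe sets, which left 12899 genes. This floor is a rule of brightness and not a detection call. Where the dimmer value lay below the floor, a lower bound of the fold against the floor is given as "at least", and log2 differences of such genes are differences of the values as measured. A gene was counted as higher or lower when the difference was at least 2-fold.

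With 1 array per population there is no replicate error and no test between the populations, so no p-values are given. Differences describe these arrays only. As the available measure of technical spread, differences of probe sets of the same detected gene were compared with each other. Their SD was 0.21 on the log2 scale over 36916 pairs, and 0.17 over the 16955 pairs in which both probe sets lay above the floor. This spread leaves out the variation between sorts, cultures and hybridizations. The number of arrays limits the precision of every value.

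33 gene lists were fixed before the data were examined, as were the floor, the fold, the alternatives and the rule for named genes. The lists covered the sort marker, liver progenitor markers, pluripotency and self-renewal, hepatocyte products, liver transcription factors, the neurotensin and CXC chemokine axis, inflammatory cytokines and NF-kappaB targets, angiogenic factors, ERK outputs, Wnt, Notch and Hedgehog genes, TGF-beta, EMT and YAP targets, and epithelial junctions. They also covered mitosis, DNA replication, hypoxia, drug efflux and aldehyde dehydrogenases, p53 targets, survival regulators, ER stress, heat shock, immediate early genes, cholesterol and fatty acid synthesis, glycolysis, interferon response, metallothioneins, histones, ribosomal proteins, housekeeping genes, blood cell markers, and endothelial and stromal markers. The platform annotation used here gave a probe set of its own to 450 of the 504 memberships. A list's median difference over its detected members was placed among 10000 random lists of the same size, matched on mean RMA level in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5, when at least 5 members were detected. The percentile describes these arrays and is not a p-value across replicates.

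The text names PROM1, the 15 genes of largest positive and of largest negative RMA difference that were also at least 2-fold changed the same way by MAS5 with the brighter MAS5 signal above 91.8, its median over probe sets, and list members of at least 2-fold or, where a list had none, its extremes. Only 10 genes met the condition for lower genes. Genes of the Y chromosome and XIST were left out of the naming. Further members were named for their role in a list's description, and this choice was made after their values were seen. Alternatives were MAS5 in place of RMA, both algorithms together, centring on the median, removal of a loess trend on level, no floor, a floor at the upper quartile of brightness, the mean over probe sets, probe sets not marked as shared, other folds, and unmatched random lists.

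The procedure was tested on simulated data made from the 12899 detected genes of this comparison, with noise of SD 0.18 (log2). Of 200 genes changed 3-fold, 100% were counted at 2-fold or more, against 48.5% of those changed by exactly 2-fold and 2.5% of those changed 1.5-fold. None of the 12699 unchanged genes was counted. The simulated noise was normal with the same SD at every brightness, so this outcome followed from the setting. The measured differences of detected genes had a larger SD of 0.32, so the simulation gives no rate of false counts for these arrays. Of 200 unchanged lists of 15 genes, 6% were called, and of lists shifted by 0.2 (log2), 92.5% were called higher. These lists were random genes with the same independent noise, so these shares also followed from the setting. They give no error rate for the measured lists. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.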

Results

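Expression was measured on 1 array of CD133+ and 1 array of CD133- cells sorted from the hepatocellular carcinoma line Huh7. CD133 is the pentaspan membrane protein encoded by PROM1 and is used as a marker of tumour-initiating liver cancer cells. The comparison asks which genes distinguish the cells that carry this marker from the cells of the same line that do not. Values are RMA log2 values unless MAS5 is named, and differences are CD133+ minus CD133-. No array was repeated, so no difference below has a replicate check.

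By RMA, the sorted populations differed most in the sort marker itself. PROM1 had an RMA value of 10.49 on the CD133+ array and 5.33 on the CD133- array, a 35.8-fold difference. On the MAS5 scale the signals were 6737 and 233, a 29.0-fold difference. The RMA difference was the largest of any detected gene, and its direction matched the labels of the sort. By MAS5 the differences of SEMA3C (6.71), LUM (5.21) and RETREG1 (5.18) exceeded that of PROM1 (4.86), each with a CD133- signal below the MAS5 floor of 91.8. The spread between probe sets of 1 gene was 0.21 on the log2 scale, against a PROM1 difference of 5.16. PROM1 was represented by a single probe set, marked as one that can match several transcripts.

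Most detected genes differed little between the arrays, although no replicate pair was available for comparison. The arrays correlated at Pearson's r = 0.994 across probe sets by RMA and at 0.923 by log2 MAS5, and 93.8% of the 12899 detected genes differed by less than 0.5 on the log2 scale. The genes that did differ were mostly higher in CD133+ cells. At least 2-fold, 213 genes were higher and 15 were lower, a share of 93.4% higher. All of these 228 genes had the same direction by MAS5, and 195 of the higher and 10 of the lower genes were also at least 2-fold changed in MAS5 signal. Both algorithms summarize the same arrays, so this agreement is not independent. Of 79 higher genes with other probe sets above the floor, 76 had the same direction on all of them and 42 were at least 2-fold on all. Of 4 such lower genes, all 4 had the same direction and 1 was at least 2-fold on all. Counted on MAS5 values alone, 548 genes were higher and 209 lower, a share of 72.4% higher. At least 4-fold in the values as measured, 45 genes were higher and 0 were lower. Some of the 45 had a CD133- value below the floor and a bound against the floor under 4-fold, such as SEMA3C (at least 1.42-fold) and RSPH1 (at least 1.12-fold). Of the 213 higher genes, 140 lay above the brightness floor in both populations and 73 only in CD133+ cells.

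**Figure D1:**
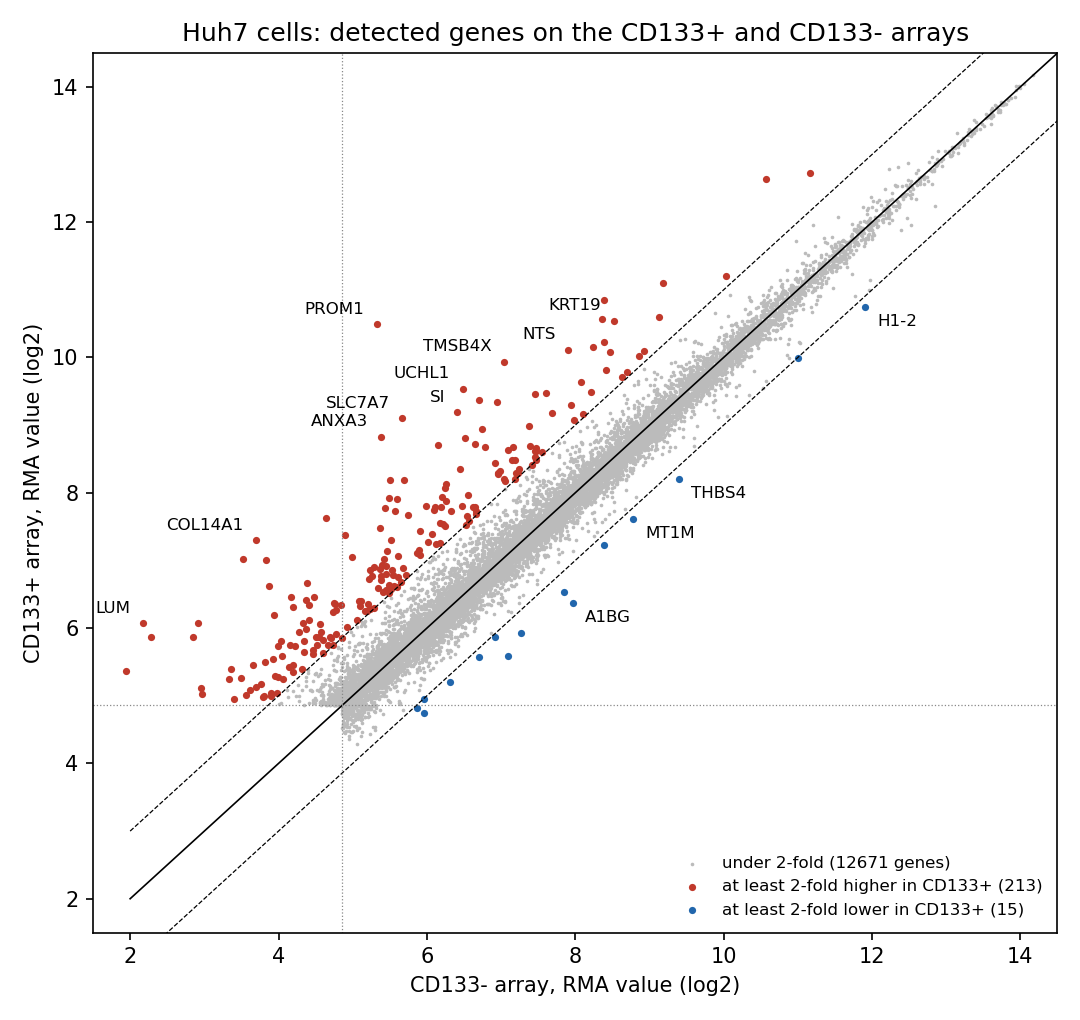
RMA value (log2) of each detected gene on the CD133- array (horizontal axis) and on the CD133+ array (vertical axis), 1 array each. Red points are the 213 genes at least 2-fold higher and blue points the 15 genes at least 2-fold lower in CD133+ cells. The solid line marks equal values, dashed lines mark 2-fold differences and dotted lines the brightness floor of 4.86. PROM1 lies farthest from the line of equal values.

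The genes of largest positive difference included extracellular matrix, secretory, intestinal and transport genes. SLC7A7, a subunit of a cationic amino acid transporter, was 10.8-fold higher, with RMA values of 9.10 and 5.67. ANXA3, a calcium-dependent phospholipid-binding annexin, was higher by 3.45 (log2). UCHL1, a ubiquitin hydrolase best known from neurons, was 8.34-fold higher, although its other probe set, below the floor, showed no difference. TMSB4X, which encodes the actin-binding peptide thymosin beta 4, was 7.46-fold higher. SI, the brush border disaccharidase sucrase-isomaltase, was 6.87-fold higher, with MAS5 signals of 2704 and 466.

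For the other 9 genes of largest positive difference the CD133- value lay below the floor, so that a bound is the safer statement. COL14A1, a fibril-associated collagen, was at least 5.42-fold higher, and its probe sets above the floor differed by 3.61 and 3.63 (log2), while those below it differed by 0.26 and -0.09. The ceramide galactosyltransferase gene UGT8 was at least 6.83-fold higher. AGR3, a disulfide isomerase family member of secretory epithelia, was at least 4.48-fold higher. KLF4, a transcription factor of epithelial differentiation and of pluripotency reprogramming, was at least 4.43-fold higher, with MAS5 signals of 609 and 45.4, while its other probe set, below the floor, differed by 0.81. The transcription factor gene TFEC and the proteoglycan gene LUM were each at least 2.33-fold higher. GBP3, an interferon-inducible guanylate-binding protein, and HEPH, an intestinal ferroxidase, were each at least 2.01-fold higher. The second HEPH probe set, also below the floor, had a difference of -0.11, and the second LUM probe set one of 0.11. SEMA3C, a secreted semaphorin, was at least 1.42-fold higher and was the gene on which the algorithms differed most among these, with differences of 3.41 by RMA and 6.71 by MAS5. Its other probe set, below the floor, differed by 0.51.

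The lower genes were fewer and smaller in size, and 4 of the 10 that both algorithms placed at 2-fold encode histones. A1BG, a plasma glycoprotein made by liver, was 3.04-fold lower in CD133+ cells, with RMA values of 6.37 and 7.97. ITIH1, a heavy chain of the liver-secreted inter-alpha-trypsin inhibitor, was 2.48-fold lower. ADH6, an alcohol dehydrogenase, was 2.24-fold lower, and its other probe set was lower by 0.90 (log2). THBS4, a matricellular thrombospondin, was 2.29-fold lower and the junction protein gene VSIG1 2.53-fold lower, although its other probe set was lower by only 0.58 (log2). The linker histone gene H1-2 was 2.25-fold lower, with MAS5 signals of 6424 and 14603, and the core histone genes H2AC17 and H4C8 were lower by 1.13 and 1.05 (log2). H2BC4, below the floor in CD133+ cells, was at least 2.14-fold lower. MT1M, a metallothionein, was 2.24-fold lower.

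**Figure D2:**
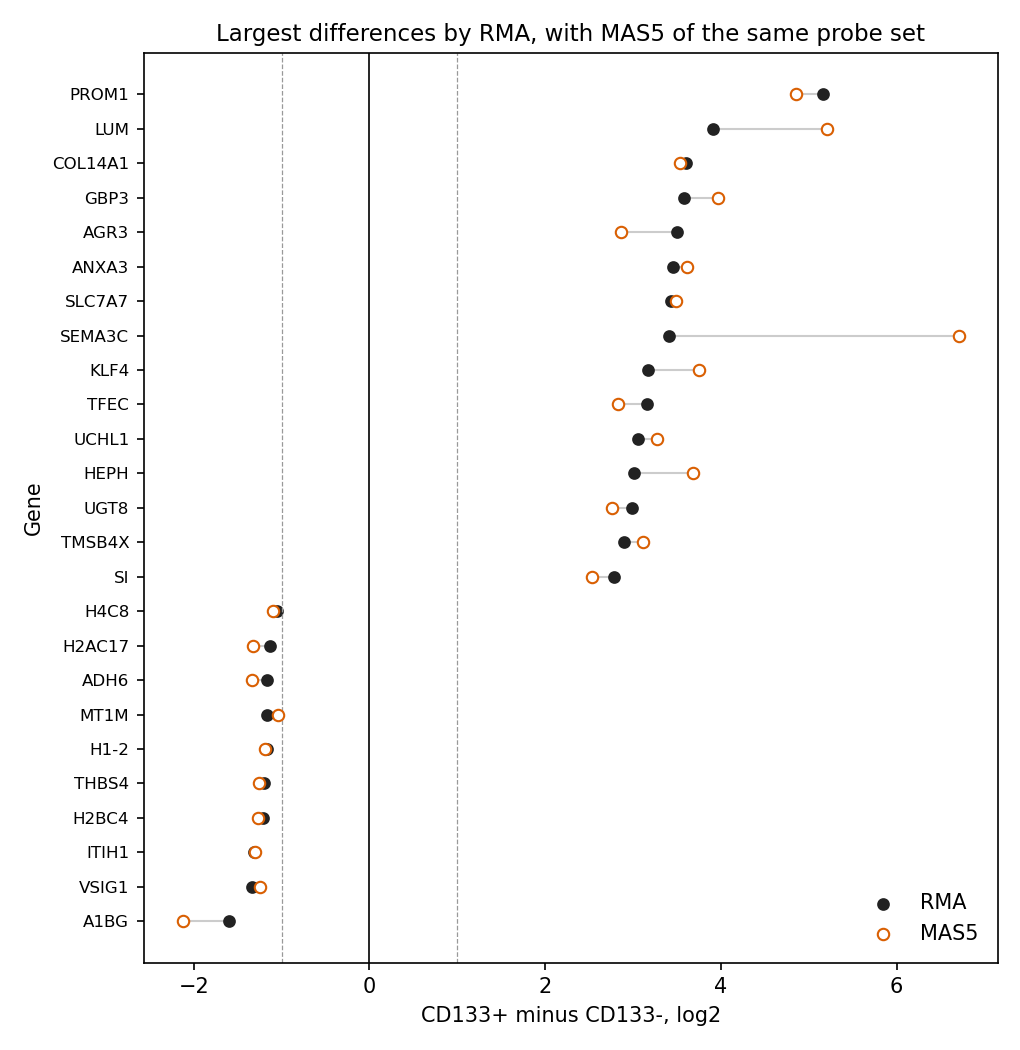
Differences CD133+ minus CD133- (log2) of the 15 genes of largest positive and the 10 of largest negative RMA difference that both algorithms placed at 2-fold or more, 1 array per population. Filled points are RMA and open points MAS5 values of the same probe set, and dashed lines mark 2-fold. PROM1 stands at 5.16 by RMA and 4.86 by MAS5, and the lowest gene, A1BG, at -1.60 and -2.13.

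Genes encoding neurotensin and CXC chemokines were higher in CD133+ cells. NTS, the gene of the peptide hormone neurotensin, was 4.63-fold higher, CXCL8 (interleukin 8) 3.09-fold and CXCL1 2.24-fold. Both CXCL8 probe sets were higher, by 1.63 and 1.92 (log2). The receptor genes NTSR1 and CXCR1 differed by 0.10 and 0.08. All 5 detected members of this list were higher, 3 of them at least 2-fold, and the median of 1.16 lay at percentile 99.99 of matched random lists. By MAS5 the receptor signals lay below the floor and CXCR1 differed by -0.15, so too few members remained for a percentile by MAS5, by both algorithms together, for bright genes or without shared probe sets. With no brightness floor, which brings in the dim members, the median was 0.10 (percentile 85.1) and the list no longer stood apart. This list was recalled as the study's own focus, chosen on these samples, and is not independent evidence of a direction.

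Inflammatory cytokines and NF-kappaB targets, a list without CXCL8 and CXCL1, shared this direction. Of 14 detected members, 13 were higher and 5 at least 2-fold: the neutrophil chemokines CXCL5 (2.77-fold), CXCL6 (2.62-fold), CXCL3 (2.41-fold) and CXCL2, just at the limit, and the cytokine IL32 (2.14-fold). The median difference was 0.54, above all but a rounding share of random lists (percentile 100). CXC chemokine genes are similar in sequence, and the CXCL2 and CXCL5 probe sets are of the kind that can take up related transcripts. IL6, TNF, CCL2 and IL1A were below the floor in both populations. Of 9 detected interferon response genes 8 were higher (median 0.44, percentile 99.99), with IFIT3 at 2.04-fold. Among 13 angiogenic growth factors the median was 0.17 (percentile 99.1), with EDN1 at 2.13-fold and PDGFA at least 1.99-fold higher, and VEGFA differed by 0.49. The median of this list was -0.0048 when MAS5 replaced RMA, and it lay inside the random range for bright genes and without shared probe sets as well.

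Epithelial genes were higher as a group. Of 13 detected junction and keratin genes, 11 were higher, with a median of 0.36 (percentile 100). CLDN7, a tight junction claudin, was 3.65-fold higher and the epithelial splicing regulator ESRP1, below the floor in CD133- cells, at least 1.83-fold. The mesenchymal filament gene VIM was also higher, 3.78-fold, as was the matricellular gene THBS1, at least 1.51-fold. The TGF-beta, EMT and YAP list they belong to had a median of 0.07 (percentile 92.0), and within it ZEB1 differed by -0.62. This depended on the method: the list stood apart by MAS5 (median 0.37, percentile 99.95), by both algorithms together, for bright genes and with the mean over probe sets.

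Liver progenitor markers went both ways. KRT19, a keratin of bile duct and progenitor cells, was 4.07-fold higher, EPCAM 2.27-fold and CD47, the "don't eat me" signal, 2.10-fold. CD44 differed by 0.91 and DLK1 by -0.82, LGR5, below the floor in CD133+ cells, was at least 1.33-fold lower, and AFP and SOX9 differed by 0.03 and -0.04. By MAS5 the CD44 difference was 3.94, with a CD133- signal of 13.1, below the MAS5 floor of 91.8. Of 17 detected members 10 were higher and 7 lower. The list median of 0.08 lay at percentile 97.7, just outside the random range, and fell inside it in 4 of the alternatives. In the pluripotency list, KLF4 was the only one of 6 detected members at 2-fold. MYC, LIN28B and SALL4 differed by -0.19, -0.23 and 0.23, and SOX2, NANOG and LIN28A were below the floor.

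Most mature hepatocyte products were similar in both populations, with exceptions in each direction. ALB, APOA1 and SERPINA1 differed by -0.05, -0.06 and -0.10. CPS1, the first committed enzyme of the urea cycle, was 5.04-fold higher, and its other probe set was higher by 2.56 (log2). PCK1, the gluconeogenic enzyme, was at least 1.42-fold higher. The arginase ARG1 was lower by 0.80 (log2), and the tyrosine catabolic enzyme HPD, below the floor in CD133+ cells, was at least 1.77-fold lower. The 26 detected members had a median of -0.07 (percentile 4.31). The list was lower than random lists for bright genes, with the mean over probe sets, and without shared probe sets, where the median was -0.31 (percentile 0). Liver transcription factors had a median of -0.01 (percentile 60.1), with FOXA3 at -0.44 and NR5A2 at 0.34.

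The listed histone and metallothionein genes were lower in CD133+ cells. All 10 detected histone genes of the list were lower, with a median of -0.81, and all 7 metallothioneins, with a median of -0.87. Both medians lay at percentile 0. MT1G was 2.01-fold lower, and MT2A was lower by 0.87 (log2). The histone variants H2AX and H2AZ1 differed by only -0.05 and -0.11. These families have near-identical copies, and all metallothionein probe sets above the floor except that of MT1M are marked as shared between transcripts, so the individual family members are uncertain.

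DNA replication genes were slightly lower and mitosis genes slightly higher. Of 19 replication genes 15 were lower, with a median of -0.16 (percentile 0.11). UNG was lowest with -0.34 and CCNE2 highest with 0.13, and MCM5 and PCNA differed by -0.33 and -0.20. Of 19 mitosis genes 13 were higher, with a median of 0.07 (percentile 98.4) and a range from -0.08 for CCNA2 to 0.33 for UBE2C. The mitosis list lay inside the random range without shared probe sets (percentile 96.9) and against unmatched lists (94.2). Lipid synthesis genes were lower by similarly small amounts. Fatty acid synthesis had a median of -0.21 over 11 genes (percentile 0.09), with SREBF1 at -0.39 and ACSL1 at 0.63. Cholesterol synthesis had a median of -0.14 over 11 genes (percentile 1.64), with MVD at -0.48 and SC5D at 0.27. The cholesterol list lay inside the random range by MAS5, by both algorithms together and against unmatched lists. None of these genes reached 2-fold, and most single differences were within about the spread between probe sets of 1 gene.

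ABCG2, the breast cancer resistance transporter, was 2.08-fold higher, and ABCB1, the multidrug transporter, was higher by 0.95 (log2). ALDH1A1 differed by -0.02. The list median was 0.06 (percentile 88.8) by RMA and 0.40 (percentile 99.98) by MAS5, and the list also stood apart by both algorithms together, for bright genes and with the mean over probe sets. DUSP4 and PHLDA1 were 2.15-fold and 2.21-fold higher among ERK outputs, whose median was -0.09 (percentile 13.2), and EGR1 differed by -0.89. BMP4 was 2.40-fold higher among Wnt targets (median -0.04, percentile 26.6), where AXIN2 differed by 0.15. CDKN1A, the cell cycle inhibitor p21, was 2.46-fold higher among p53 targets (median -0.12, percentile 8.04), and TP53INP1 differed by -0.04. The Notch list had a median of 0.10 (percentile 95.2), with JAG1 at 0.47 and NOTCH1 at -0.54, and the Hedgehog list one of 0.02 (percentile 53.4), with IHH at 0.21 and PTCH1 at -0.50. Survival regulators had a median of 0.09 (percentile 95.4), from BCL2L11 at -0.12 to BCL2L1 at 0.31. Hypoxia targets had a median of 0.04 (percentile 86.5), from EGLN3 at -0.34 to ENO2, below the floor in CD133- cells, at 0.67. ER stress genes had a median of -0.06 (percentile 19.1), from XBP1 at -0.24 to ATF3 at 0.37. Glycolysis genes had a median of -0.01 (percentile 63.7), from PFKM at -0.07 to HK1 at 0.54. In some alternatives further lists stood apart: Notch (percentile 99.5) and ERK (1.4) with the mean over probe sets, and survival regulators (99.3) for bright genes. Hypoxia (99.8) and glycolysis (99.7) did so without shared probe sets, and by both algorithms together (98.85 and 97.64). These lists share members, and both had a median of 0.23 without shared probe sets.

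**Figure D3:**
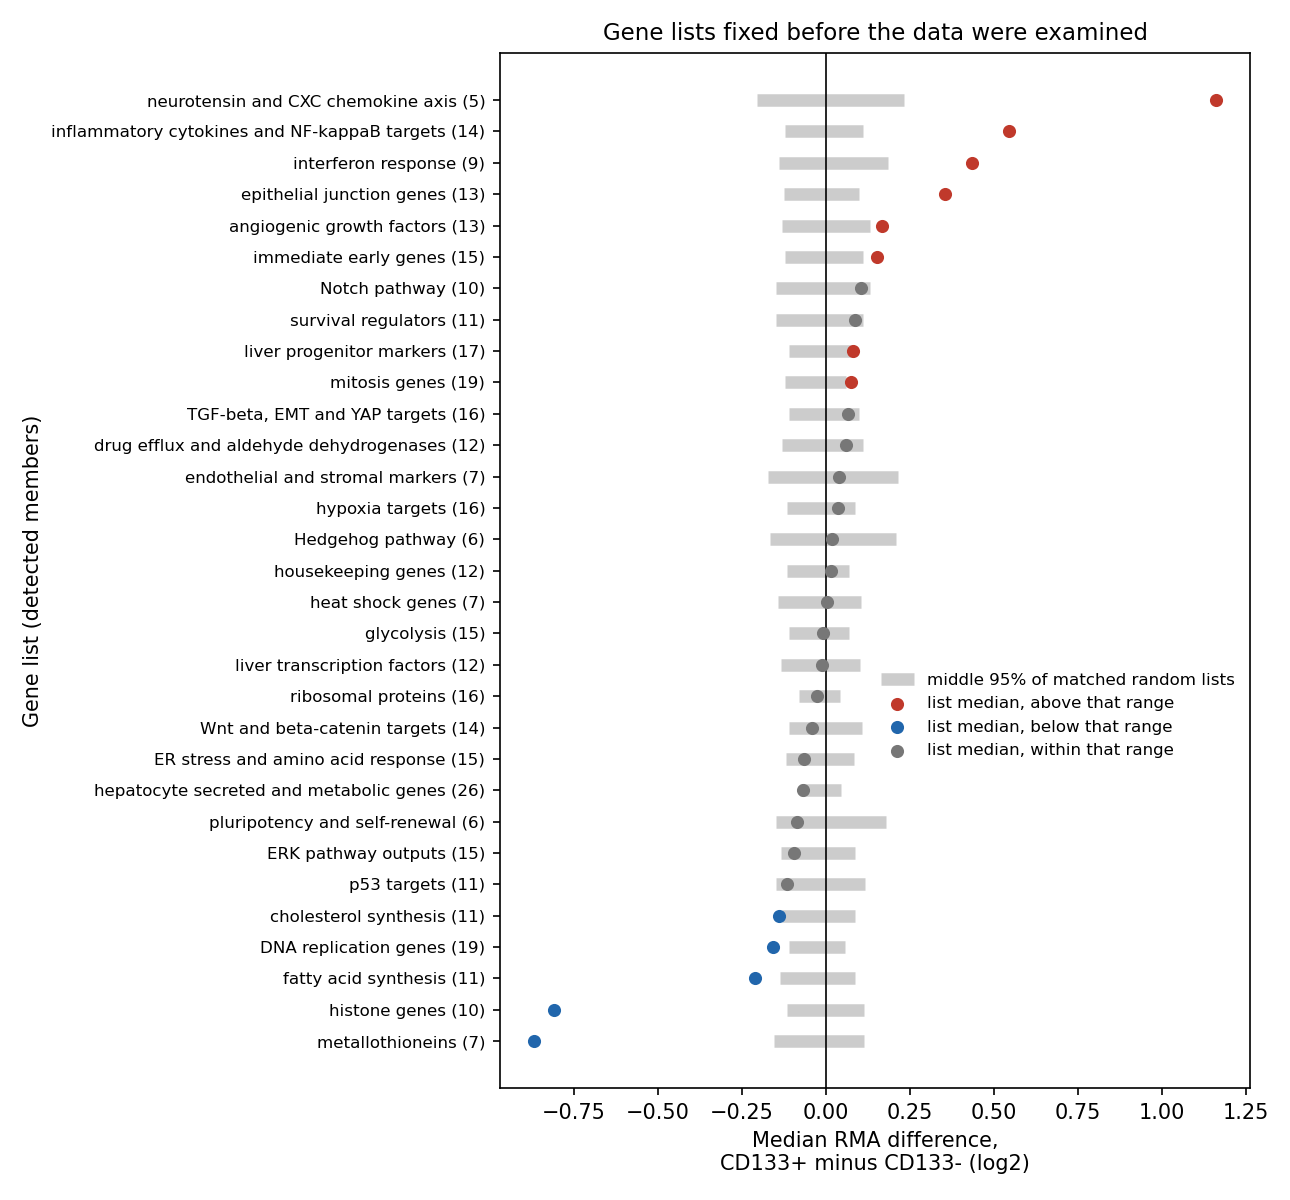
Median RMA difference (log2, CD133+ minus CD133-) of the detected members of 31 gene lists, with the number of detected members in parentheses. Grey bars are the middle 95% of medians of 10000 random lists matched on level. Of the 31 lists 8 lie above and 5 below that range, with the neurotensin and CXC chemokine axis at 1.16 and metallothioneins at -0.87 as the extremes.

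In all, 13 of the 31 lists with enough detected members stood apart, 8 of them higher and 5 lower. Random lists of independently drawn genes would give 1.55. Members of a real list can vary together or share probe sets, so 1.55 is not the chance count for these lists. The 8 higher lists include the neurotensin and CXC chemokine list, which was recalled as chosen on these samples. The inflammatory, interferon, junction, DNA replication, fatty acid, metallothionein and histone lists stood apart in every alternative that left enough members, and the other 6 lost their call in at least 1. Median and mean differed in sign for the pluripotency, hepatocyte, ERK, Wnt, Hedgehog, p53, ER stress, heat shock and glycolysis lists, so their medians hide single genes of the opposite direction.

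Markers of other cells and of handling were measured alongside. Blood cell markers had 4 detected members, too few for a percentile, with CD14 at -0.25 and HBB at 0.00. Endothelial and stromal markers had a median of 0.04 (percentile 61.0), but LUM and COL1A2 were among the higher genes, COL1A2 by 2.51-fold, while DCN, COL3A1 and ACTA2 were below the floor. Immediate early genes, which respond to cell handling, had a median of 0.15 (percentile 99.5), inside the random range by MAS5 (89.0) and by both algorithms together (94.8). Of the 15 detected members 11 were higher and 4 lower. KLF4 belongs to them, FOS and JUN differed by 0.39 and 0.06, and EGR1, also a member, was lower. Heat shock genes had a median of 0.00 (percentile 70.9), from HSPE1 at -0.25 to HSPB1 at 0.25. Ribosomal protein genes had a median of -0.03 (percentile 45.1), from RPL27 at -0.09 to RPL8 at 0.03, and housekeeping genes one of 0.02 (percentile 84.9), from TBP at -0.24 to PGK1 at 0.33. The MAS5 ratio of 3' to 5' control probe sets was 1.15 on the CD133+ array and 1.24 on the CD133- array for ACTB, and 0.952 and 1.01 for GAPDH. The 18 hybridization spike probe sets differed by between -0.003 and 0.10. The 24 poly-A spike probe sets, which pass through amplification and labelling, differed by between -0.35 and 0.13 (median -0.07). Among the lists that stood apart, the replication, mitosis, cholesterol, fatty acid and liver progenitor medians lay inside that range. The immediate early (0.15) and angiogenic (0.17) medians lay just above it. That range is of single spike probe sets, while the list values are medians over several genes. The comparison therefore does not show that these medians are technical. The 3 probe sets for 18S ribosomal RNA were higher in CD133+ cells by 0.20 to 0.54.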

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

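Outside the named genes, 4155 probe sets above the brightness floor had no single gene in the platform annotation used here. Of these, 22 were at least 2-fold higher in CD133+ than in CD133- cells by both RMA and MAS5, and 1 was at least 2-fold lower. They were singled out because they carry signal that the comparison of named genes leaves out. No explanation was tested, and the populations had 1 array each, so outlying samples could not be looked for.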

How the results depend on the processing

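No paired analysis was possible because each population has 1 array, and for the same reason no replicate could be left out. PROM1 differed by 4.86 by MAS5 and by between 5.01 and 5.20 in the other alternatives that changed its value. The 213 higher and 15 lower genes became 548 and 209 by MAS5, 474 and 130 at 1.5-fold, and 83 and 1 at 3-fold. With a floor at the upper quartile of brightness there were 117 higher genes, and 10 lower. In the remaining settings both counts stayed within 1.5 times. A setting chosen after seeing the data, MAS5 with its own upper quartile of brightness, gave 158 and 19. The correlation of RMA and MAS5 differences across detected genes, which are not independent, was 0.60 (Spearman's rho 0.65). It was 0.42 with no floor, 0.86 in the upper quartile and 0.56 without shared probe sets. Between 10 and 17 lists stood apart in every alternative, and between 8 and 12 of the 13 kept their call where any was lost, partly because fewer members remained under stricter settings. The angiogenic list turned to -0.0048 by MAS5, and HEPH to -0.11 on its other probe set; the cause was not tested. Among the genes named for the largest differences, 9 moved with the mean over probe sets, and VSIG1 (-0.96) then lay under 2-fold. Centring shifted nothing, since the median difference was 0, and so tested nothing.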

Other observations

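The tests on brightness, normalization and shared probe sets of listed histone genes below, the division of the kidney list, and the choice of the gene lists of tissues and of the urea cycle, were made after the differences of the largest genes had been seen; the tests on gut list members and histone genes not yet seen, on abundant gut genes and on replication genes were set before their values were known.

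Genes of gut epithelium were among the higher genes. Of 36 detected members of a list of 45, 30 were higher and 15 at least 2-fold, with a median of 0.73, but 10 of these 15 had been seen when the list was written. Besides SI, they included the brush border annexin ANXA13 (6.39-fold), the mucin MUC13 (5.92-fold), the secretory isomerase AGR2 (5.52-fold), the cadherin CDH17 (4.63-fold), the chloride exchanger SLC26A3 (4.56-fold) and the carbonic anhydrase CA4 (4.23-fold). The gut transcription factor CDX2 differed by 0.69. Genes of kidney proximal tubule were higher as well (median 0.48, percentile 99.99), among them the endocytic receptor LRP2 (3.15-fold) and SLC3A1 (at least 3.05-fold). That list included genes already seen, and the 11 detected members not yet seen when it was written had a median of 0.23 (percentile 99.6), or 0.06 (percentile 78.3) with no floor. Stomach genes had a median of 0.25 (percentile 99.5) over 8 detected members, 5 of them higher and 3 lower. TFF1 was 3.60-fold higher, while 1 other member was at least 2-fold lower. Bile duct genes had a median of 0.11 (percentile 95.4). Without shared probe sets these turned to 0.01 (percentile 60.7) for stomach and 0.24 (percentile 99.4) for bile duct, so neither is firm. Neuron, lung and muscle lists, written as comparators, lay at percentiles 89.7, 20.3 and 54.6 by RMA. By MAS5 lung (percentile 0.25) and muscle (98.2) stood apart, and neurons did so with the mean over probe sets (99.1) and by both algorithms together (98.6), so these lists are not neutral on every scale. Gut genes stood apart in all alternatives. The pancreatic acinar genes had only 4 detected members.

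In the urea cycle, CPS1 went against its pathway. CPS1 was 5.04-fold higher, and the other 6 genes were lower, from -0.87 for OTC, -0.80 for ARG1 and -0.79 for NAGS, which makes the activator of CPS1, to -0.13 for ASL. The median over the 7 genes was -0.32, inside the range of the poly-A spike probe sets (-0.35 to 0.13).

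The gut genes might form a gene group rather than a few picked genes. The 26 detected members whose values had not been seen had a median of 0.38, at percentile 100 of matched random lists, and TRIM31, DPP4, TFF3 and GUCY2C were at least 2-fold higher, with LCT, dim in CD133- cells, at least 1.49-fold. Admixed intestinal or colorectal cells would bring abundant gut transcripts, but only 1 of 8 such genes, TFF3, was detected and at least 2-fold higher. KRT20 and PHGR1 stayed below the floor with RMA values of 3.25 and 3.90 in CD133+ cells. A gene already bright in CD133- cells can miss 2-fold, and gut genes outside these 8, such as CDH17 and AGR2, were higher. The 8 genes alone therefore do not exclude admixture. A wider group that takes in kidney transport genes stays open. A difference between CD133+ and CD133- cells themselves stays a hypothesis that a single array per population cannot test.

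The excess of higher over lower genes is unlikely to be noise of dim probe sets alone, since the ratio was 11.7 among genes in the upper quartile of brightness, against 14.2 among all detected genes. The RMA normalization was first tested by the MAS5 ratio of all detected genes, 2.62, which fell between the limits of 1.5 and 3 set for it and left the question open for dim genes. Only then was the test repeated on bright genes, where MAS5 gave a ratio of 8.32, which argues against the RMA normalization as the whole cause there. A property of the sort stays open and was not tested: CD133- cells left in the CD133+ gate would shrink the lower genes.

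Lower histone values were not confined to probe sets marked as shared. How far hybridization of near-identical copies to shared probe sets contributes to them stays open. The 5 listed histone probe sets not marked as shared had a median of -1.17, but 3 of them belong to genes that had prompted the test. Among 12 unshared probe sets of histone genes not yet seen 10 were lower, with a median of -0.37, between the limits of -0.3 and -0.5 set for this test. Fewer cells in S phase would be consistent with the DNA replication list at percentile 0.11. Its median of -0.16 is small beside -0.81 for histones, the mitosis list was slightly higher (median 0.07), and RNA processing or labelling differences between histone and other transcripts were not tested.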
